A study of Drosophila melanogaster with 2 samples.

How the data were processed

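The series measured the places where a CG15269-eGFP fusion protein was recovered by ChIP-seq with, per the sample descriptions, an antibody against GFP in whole mixed-sex embryos of 6 to 18 h. This age is that of the source name, and the age field of the labels holds another value. The series holds 2 biological replicates of 1 group, numbered 2 and 3. Per the labels, chromatin was sheared by sonication to fragments of 200 to 800 bp and the assembly was dm6. The labels name control alignments, which are not analysed here. The aligner, the peak caller, its settings and the IDR threshold are not given in the sources used here.

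The authors deposited 4 peak lists in narrowPeak format. Peaks had been called on each replicate separately and on both replicates together, each against a control, per the text files deposited beside the samples, and an IDR-thresholded list had been derived from these. Each list gives a signal per peak, which is the value deposited by the authors on a scale that is not given in the sources used here, and a -log10 q-value per peak, also as deposited by the authors. The deposited summit offset gives the position of the summit within the peak. The 3 unthresholded lists held exactly 30000 peaks each. The 7029 peaks of the IDR list were the same peaks as the 7029 strongest of the list called on both replicates together, with equal signals, and all had the same -log10 q of 4.20, so only the signal ranks them. No read totals are in the files, so depth is unknown, and signals were not compared between lists except by rank correlation and by Pearson's r of matched peaks.

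Gene positions came from Ensembl release 115 and sequence from the RefSeq copy of the release 6 genome, whose coordinates are those of dm6. The list of zinc finger genes was taken from product names in the RefSeq annotation. The analysis used the 6 arms that carry peaks, 18164 genes without transposable elements, 13945 of them protein-coding, and 23998 TSSs. Peaks counted as overlapping when they shared at least 1 bp. A summit was near a TSS within 500 bp. Location classes were assigned in the order TSS, 5' UTR, coding exon, 3' UTR, intron, other exon and intergenic. Random placements kept the arm of each summit, left out runs of N and were drawn 1000 times. Shares have exact Clopper-Pearson 95% intervals. Gene lists, consensus sequences, tests and the first set of alternatives were fixed before the data were examined. Of the names in the gene lists, 12 matched no protein-coding gene on the arms.

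Arm shares were tested with exact binomial tests, gene lists and head-to-head promoters with Fisher's exact test, and known consensus sequences with exact sign tests on pairs of a 201 bp summit window and a 201 bp window centred 400 bp away on a side drawn at random. Words of 8 bases were counted in 101 bp windows, with reverse complements merged, and tested with Fisher's exact test where at least 20 windows held the word. Benjamini-Hochberg adjustment was made within each family with a threshold of 0.05. Control windows of equal A+T content were drawn from 300 to 3000 bp around the summits and at least 300 bp from any IDR summit, and had the same number of A and T bases as the summit window. They were not paired with their own peak and a window could be drawn more than once, and were compared by Fisher's exact test.

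Genes were named by a rule fixed beforehand: those within 500 bp of the 25 strongest IDR peaks that have a protein-coding TSS, at most 2 per peak, the 5 strongest peaks and the strongest of each arm, up to 4 bound members of each gene list with the highest signal and any member of lists of at most 8, and CG15269. Examples of these are given, and some genes that the rule takes are not reported here. A gene's value is the highest signal of a summit within 500 bp of any of its TSSs.

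The statistics were tested on simulated data. With 7029 random positions of which 30% were moved to TSSs, the share near a TSS was 39.9% where 39.5% was due. With bound genes drawn at random, 2 lists were called in 100 simulated sets of 32 lists over 13945 genes. Genes were drawn independently there, while in the data 1 summit can bind both genes of a head-to-head pair. For words of 8 bases, 0 of 30919 were called at random positions, and a word placed in 3% of the windows ranked 1. For the 18 consensus sequences 0 were called at random positions. Random positions lack the A+T content and the closeness to TSSs of the IDR summits. The simulated rates of false calls therefore need not hold for the tests on the data.

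Alternatives were other TSS windows, stricter peaks, each replicate's list alone, the list called on both replicates together, other overlap rules, backgrounds, flanks, word lengths, bins and distances. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.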

Results

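Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole mixed-sex embryos of Drosophila melanogaster, aged 6 to 18 h by their source name (the age field of the labels holds another value), from a transgenic line in which the protein encoded by CG15269 carries a C-terminal eGFP tag. Per the sample descriptions, DNA bound by the fusion protein was recovered with an antibody against GFP, while the antibody field of the labels names CG15269. The series holds 1 group with 2 biological replicates, numbered 2 and 3 in the labels, and no treated or untreated counterpart, so the design asks where the tagged protein was recovered and whether both replicates gave the same places. The files list peaks with a signal per peak and hold no read totals, so the sequencing depth of each replicate is unknown. All positions are on assembly dm6, counted from 1. The intervals below are exact Clopper-Pearson 95% intervals and cover counting error only. Peaks and genes are not biological replicates, so p-values computed over them describe these libraries.

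The strongest peak lay on arm 3L (start 19590384, end 19590860), with its summit at 19590614 in intergenic sequence 90 bp upstream of the transcription start site (TSS) of CG14100 (FBgn0036889). Its signal was 8020, where the signal is the authors' own value per peak, on a scale not given in the sources used here. The peak ranked next lay on 2L (480517 to 481354, signal 8018), in an intron of ush and 1399 bp upstream of the TSS of cbt. It was followed by a peak in an intron of CG11050 on 2L (6612442 to 6612947, signal 7512), a peak 37 bp upstream of Ugalt, a UDP-galactose transporter gene on X (2703660 to 2704129, signal 7318), and a peak 144 bp upstream of mRpL41, a mitochondrial ribosomal protein gene on 2R (15217560 to 15218006, signal 6968). The strongest peak of 3R lay 128 bp upstream of CG18549 (12448932 to 12449389, signal 5813). The strongest peak of chromosome 4 ranked 734 in the list (424670 to 424975, signal 934) and was intergenic, 19086 bp from the nearest protein-coding TSS, that of lgs.

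In all, 7029 peaks passed the authors' threshold on the irreproducible discovery rate (IDR). Their median width was 369 bp and their median signal 288. Chromosome 4 held 12 of them, 8.90 per Mb, against 48.8 to 55.7 per Mb on the other arms. That was 0.171% of the peaks (interval 0.0882 to 0.298%) on 1.01% of the sequence, a ratio of 0.170 (exact binomial test, two-sided, Benjamini-Hochberg adjusted p = 6.41e-17). Shares of sequence count all bases. How much of each arm can be read uniquely was not analysed here. Departures on the other arms were small, with ratios of 0.930 on 2R (exact adjusted p = 0.0138), 1.06 on 3L (0.0208) and 1.06 on X (0.0294), and those of 2L (adjusted p = 0.204) and 3R (adjusted p = 0.175) did not pass. The calls on 2R, 3L and X were not made from replicate 2 alone, where the ratios were 0.959, 1.04 and 1.03, and that on 3L was not made in the 3514 strongest peaks (exact adjusted p = 0.967).

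The replicates were compared first through the places they share. Of the 7029 strongest peaks of replicate 2, 77.7% (interval 76.7 to 78.7%) overlapped by at least 1 bp a peak among the 7029 strongest of replicate 3. When the same peaks were placed at random on their arms, the mean share was 3.27% and the highest of 1000 draws was 4.0%. The share was 83.3% among the 1000 strongest peaks. Both replicate lists held a peak at 97.8% of the IDR peaks, which is in part built in, since the IDR list was derived from them. Across the 6872 IDR peaks matched in both lists, the signals of the replicates had a Spearman rank correlation of 0.761 and a Pearson r of 0.945. The summits of the replicates lay a median of 24 bp apart.

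Summits were concentrated next to TSSs and nearly absent from coding exons. Of the 7029 summits, 2755 lay within 500 bp of an annotated TSS, 39.2% (interval 38.1 to 40.3%) against 13.6% with random placement on the same arm, a 2.88-fold difference (one-sided permutation p = 0.001, the smallest that 1000 draws can give). Coding exons held 13 summits, 0.185% against 13.7% at random. The 3' UTRs held 0.982% against 4.42% and intergenic sequence 15.4% against 27.2%. Each of these classes differed from random placement (two-sided permutation test, p = 0.002, the smallest that 1000 draws can give, adjusted p = 0.00233). Introns held 42.8% of the summits against 39.5% at random (permutation adjusted p = 0.00233), but this excess was not found against the weakest 7029 peaks of the list called on both replicates together, of which 50.9% were intronic. In those weakest peaks 15.02% of summits were near a TSS, 2.59% in coding exons and 2.12% in 3' UTRs, so that the ratios for coding exons and 3' UTRs were 0.0714 and 0.463 against them and 0.0135 and 0.222 against random placement.

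**Figure D1:**
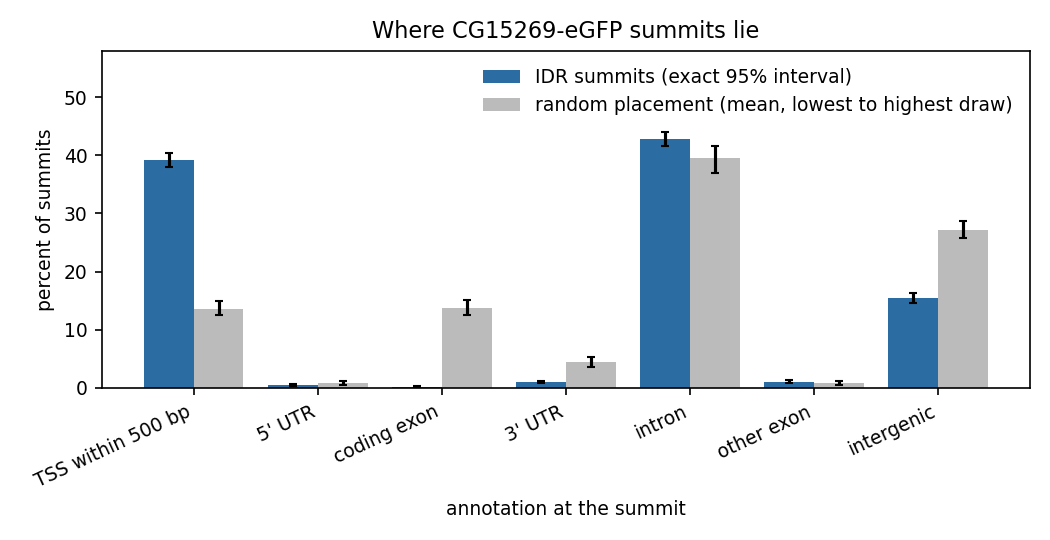
Percent of the 7029 IDR summits in each annotation class (blue, exact 95% intervals) and of summits placed at random on the same arm (grey, mean with the lowest and highest of 1000 draws). Summits within 500 bp of a TSS make up 39.2% against 13.6% at random, and coding exons hold 0.185% against 13.7%.

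Around protein-coding genes the summits lay on the upstream side. Of 2557 summits within 500 bp of a protein-coding TSS, 1981 (77.5%) were upstream of it, and the median position was -123 bp. The fullest 50 bp bin, from -150 to -100 bp, held 412 summits against 41.3 at random. Between 150 and 350 bp downstream there were 66 summits against 174 at random.

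**Figure D2:**
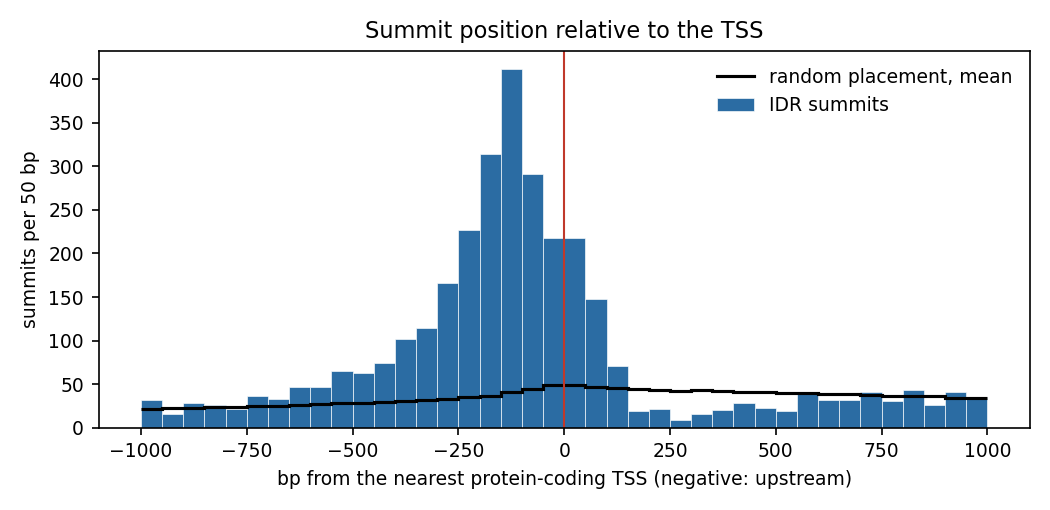
Number of IDR summits per 50 bp by distance from the nearest protein-coding TSS, negative values being upstream (blue bars), and the mean of random placements (black line). The fullest bin, from -150 to -100 bp, holds 412 summits against 41.3 at random.

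The 25 strongest peaks within 500 bp of a protein-coding TSS ranked between 1 and 34 in the list, and 22 of them had the summit upstream of the nearest TSS. Genes of mitochondrial translation and RNA metabolism were among them: mRpL41, mRpS10, whose TSS shares a peak with the arginine methyltransferase gene Art3 on 3R (15229313 to 15229748, signal 5624), mRpS23, which shares one with the Arf GTPase-activating gene CenG1A on 2L (13835264 to 13835707, signal 4806), and PNPase, the gene of polynucleotide phosphorylase, on 3R (31404440 to 31404881, signal 5608, summit in the 5' UTR). Genes of chromatin factors included ph-p, a Polycomb group gene on X (2136987 to 2137606, signal 5461), and Chro, a chromodomain protein gene on 3L, whose peak also lay 195 bp from the TSS of the TFIIH subunit gene Ssl1 (22878688 to 22879135, signal 4372). Other genes of the set were Gapdh2, a glycolytic enzyme gene on X (15867743 to 15868244, signal 5107), Fkbp14, Pal1 with Pdrg1, eIF4EHP, which codes for a cap-binding translational repressor, with CG18428, Fbw5 with CG9147, px, Tcs5 with the ESCRT-III gene CHMP2B, RluA-1, Tina-1, Mtl with CG5611, the casein kinase gene gish, larp, CG1635, CG1888, CG13390 with CG17294, and CG31145. Their signals lay between 3851 and 5107. At some shared peaks the gene named first was the farther one. The TSS of mRpS23 lay 384 bp from the summit and that of CenG1A 108 bp. For eIF4EHP and CG18428 the distances were 250 and 126 bp, and for Mtl and CG5611 250 and 102 bp. Of all 123 genes taken by the naming rule, 88 were bound within 200 bp of a TSS.

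In total 2876 of 13945 protein-coding genes (20.6%) had an IDR summit within 500 bp of a TSS and are called bound here. Ribosomal protein genes were bound far more often than other genes: 66 of 92, or 71.7% (interval 61.4 to 80.6%), against 20.3% (Fisher's exact test, odds ratio 9.98, p = 5.37e-26, adjusted p = 1.72e-24 over 32 lists). The strongest peaks among them were at RpL34b (signal 1482), RpS27 (1286) and RpL7 (1178). Genes of other classes used in all cells were not set apart: 14 of 52 translation factor genes, 20 of 87 genes of the tricarboxylic acid cycle and respiratory chain, 7 of 48 proteasome genes, 5 of 22 splicing genes, 3 of 21 nuclear pore genes and 10 of 35 genes of DNA replication and the cell cycle were bound, with exact adjusted p between 0.507 and 0.846. Of the mitochondrial ribosomal protein genes 24 of 73 were bound (32.9%, exact p = 0.0132, adjusted p = 0.0528).

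Genes of insulator and promoter architecture proteins were bound in 10 of 21 cases (47.6%, odds ratio 3.51, exact adjusted p = 0.0244), with the strongest peaks at Chro (signal 4372), Cp190 (2730), M1BP (904) and Trl, the gene of the GAGA factor (868). This call was made again without replicate 2 (exact adjusted p = 0.0348), but not without replicate 3 (0.0691), in the 3514 strongest peaks (0.0717), within 200 bp (0.0801) or 1000 bp (0.0588) of a TSS, or among genes near any peak called on both replicates together (0.347). With 1 gene counted per peak 4 of 21 were bound (exact adjusted p = 0.873). In the Polycomb and Trithorax groups 12 of 31 genes were bound (exact adjusted p = 0.0737), among them ph-p, brm (2543) and E(z) (1947). In the Notch pathway 7 of 16 were bound (exact adjusted p = 0.0905), among them gro (1422), aph-1 (1325) and numb (1206), and in the Enhancer of split complex 5 of 11 (adjusted p = 0.139). The Notch pathway list passed without replicate 3, with 9 of 16 genes (exact adjusted p = 0.0105), within 1000 bp of a TSS (0.0221) and with 1 gene counted per peak (0.0423), and its adjusted p was 0.305 without replicate 2. The Polycomb and Trithorax list passed without replicate 2 (exact adjusted p = 0.0470) and within 200 bp of a TSS (0.0142). The mitochondrial ribosomal protein list passed in the same alternatives (exact adjusted p = 0.0470 and 0.0317), while with 1 gene counted per peak 12 of its 73 genes were bound (0.963).

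Lists of developmental regulators and tissue markers gave no call in the main analysis, and some did in alternatives. Other developmental signals passed as higher without replicate 3 (exact adjusted p = 0.0107), within 1000 bp of a TSS (0.00613) and with 1 gene counted per peak (0.0233). Trachea passed without replicate 3 (exact adjusted p = 0.0277) and epidermis and cuticle within 1000 bp (0.0102). Bound members numbered 15 of 44 for other developmental signals (sgg with signal 2090, spi with 1796), 7 of 17 for epidermis and cuticle, 4 of 10 for trachea, 8 of 25 for heat shock genes (Hsp27 with 1819), 5 of 15 for annotated zinc finger genes, 10 of 42 for mesoderm and muscle (Msp300 with 1606, sls with 1571), 8 of 45 for neural development and neurons (elav, a neuronal RNA-binding protein gene, with 2814), 5 of 32 for segmentation genes (nkd with 1359), 3 of 11 for salivary gland, 3 of 13 for germ cells, 2 of 10 for midgut and endoderm, and 2 of 17 for blood cells and fat body. None of the 8 Hox genes (upper end of the interval 36.9%) and none of the 6 dosage compensation genes (45.9%) was bound, and neither list passed (exact adjusted p = 0.545).

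Several gene families were bound less often than other genes. No chemoreceptor gene of 179 was bound (upper end of the interval 2.04%, exact adjusted p = 2.53e-17), no testis-specific gene of 25 (adjusted p = 0.0244), 3 of 51 odorant binding protein genes (adjusted p = 0.0244) and 3 of 70 cuticular protein genes (Cpr65Ea, Cpr67Fa1 and Cpr65Av, adjusted p = 0.00132). The calls on testis-specific, odorant binding protein and histone genes were not made among genes near any peak called on both replicates together (Fisher's exact test, adjusted p = 0.558, 0.757 and 1), where 2, 8 and 4 of their genes were tested. Those on the testis-specific and odorant binding protein lists were also not made in the 3514 strongest peaks or with 1 gene counted per peak, and that on the testis-specific list not within 200 bp of a TSS (0.129), with adjusted p from 0.00736 and 0.00613 upwards over their alternatives by the exact test. None of 20 eggshell and yolk genes was bound (exact p = 0.0220, adjusted p = 0.0737, with adjusted p = 0.0470 without replicate 2 and 0.0221 within 1000 bp). Of 115 histone genes 2 were bound, His2Av and His3.3B, which are both variants outside the repeated cluster (exact adjusted p = 2.08e-08). Where members are repeated copies, peaks depend on how the authors treated reads that map to several places, which is not given in the sources used here, and how far this accounts for the call was not analysed here.

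**Figure D3:**
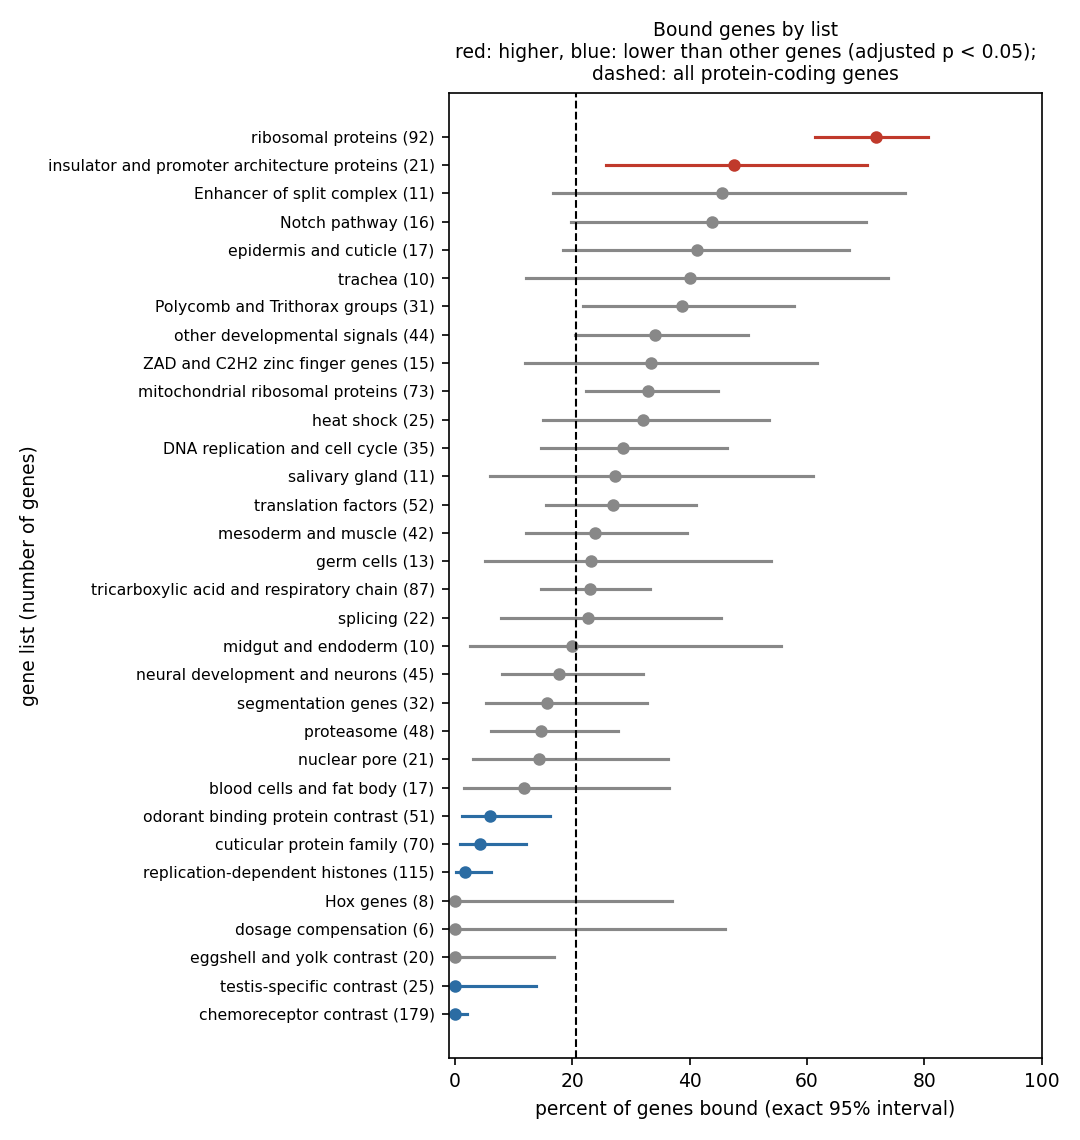
Percent of each list's genes with an IDR summit within 500 bp of a TSS, with exact 95% intervals and the number of genes in brackets. The dashed line is the 20.6% of all protein-coding genes. Ribosomal protein genes lie highest at 71.7%, and chemoreceptor genes are at 0 of 179.

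Bound genes more often had a head-to-head neighbour. A TSS on the opposite strand within 1000 bp upstream was found for 1586 of 2876 bound genes (55.1%) and 3466 of 11069 unbound genes (31.3%; Fisher's exact test, odds ratio 2.70, p = 5.77e-120). A summit between a pair of such TSSs counts for both genes. With 1 gene counted per peak the odds ratio was 1.44 (exact p = 1.90e-14). Under that rule the farther gene of a shared peak counts as unbound unless another summit binds it. Of the unbound genes 4084 of 11717 (34.9%) then had a head-to-head neighbour, so this ratio is not a corrected estimate.

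Among genes without a protein product, 33 of 290 tRNA genes (11.4%) had a summit within 500 bp, against 5.10% with random placement (two-sided permutation test, p = 0.002, the smallest that 1000 draws can give, adjusted p = 0.005), and 193 of 1944 lncRNA genes (9.93%) against 5.29% (adjusted p = 0.005). The tRNA result was not found without replicate 2 (1.62-fold, permutation adjusted p = 0.147) or in the 3514 strongest peaks (1.61-fold, 0.410). The counts of 25 of 269 snoRNA genes, 5 of 32 snRNA genes and 0 of 99 rRNA genes did not pass (permutation adjusted p = 0.0849, 0.0766 and 0.282). The snRNA genes passed in the 3514 strongest peaks (5.76-fold, permutation adjusted p = 0.0350) and without replicate 3 (3.71-fold, 0.0400), and the snoRNA genes within 1000 bp (2.48-fold, 0.00333). Of all IDR summits, 36.4% lay within 500 bp of a protein-coding TSS, against 11.5% with random placement. The random placements did not keep this closeness. These tests therefore cannot separate summits at genes without a protein product from summits at protein-coding promoters beside them.

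The DNA at the summits was rich in A and T. In the 51 bp at the summit the A+T content was 67.0% ± 11.2 (SD over 7029 peaks), against 58.1% at 1000 bp on either side. It was 66.1% at summits within 500 bp of a protein-coding TSS and 67.6% farther away, while unbound positions at the same distances from TSSs had 59.9% and the weakest peaks called on both replicates together had 58.2%. In the 1757 IDR peaks with the highest signal it was 70.8% and in the 1758 with the lowest 64.2% (Spearman rank correlation of signal and A+T content across peaks 0.222).

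**Figure D4:**
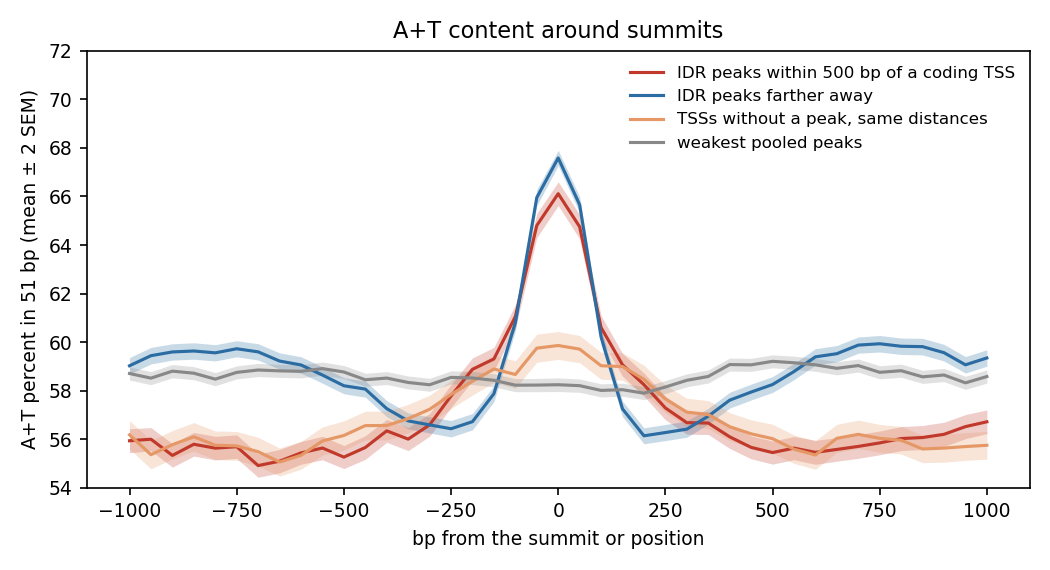
Mean A+T percent in 51 bp windows (shaded, 2 SEM either side) by distance in bp from IDR summits near and far from a protein-coding TSS, from unbound positions at the same TSS distances, and from the weakest peaks called on both replicates together. Both sets of IDR summits rise to 66.1 and 67.6% at the centre, and the weakest peaks stay at 58.2%.

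Sequences at the summits were searched for 18 known consensus sequences within 100 bp and compared with a window of the same length centred 400 bp away. The DRE, the TATCGATA element bound by Dref and BEAF-32, was present at 141 summits and 41 flanks (2.01 and 0.583%, exact sign test, adjusted p = 8.24e-14). The M1BP consensus GGTCACACT was present at 70 summits and 22 flanks (exact adjusted p = 5.54e-07). Both were also higher against windows of equal A+T content, an alternative chosen after the data were seen (2.88-fold, exact adjusted p = 2.15e-10 for DRE, and 5.83-fold, adjusted p = 3.28e-10 for M1BP). Within 50 bp of summits the DRE was 1.85-fold higher than in flanks in place of 3.44-fold (exact adjusted p = 0.0211), and in the 3514 strongest peaks the M1BP consensus was 2.08-fold in place of 3.18-fold (0.0461). Neither passed at the 4274 summits farther than 500 bp from a TSS, where DRE was found at 19 summits and 14 flanks and M1BP at 8 and 5 (exact adjusted p = 0.532 and 0.615). Neither kind of control window was matched for distance from a TSS. These comparisons therefore cannot separate sites of the tagged protein from promoters in general.

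Of the other consensus sequences, 6 were higher and 7 lower at summits than in flanks. The TATA box (9.30 against 3.96%), the homeodomain site TAATTA (18.7 against 12.0%), the GATA site (30.5 against 22.4%), core promoter motif 6 and the Su(Hw) consensus were higher than in flanks but not than in windows of equal A+T content (exact adjusted p between 0.191 and 0.670). The poly-A tract was higher than in flanks (1.23-fold) and lower than in windows of equal A+T content (0.906-fold, exact adjusted p = 0.0213). The CTCF consensus AGRKGGC was lower than in flanks (6.10 against 8.22%, exact adjusted p = 2.13e-06) and higher than in windows of equal A+T content (1.41-fold, adjusted p = 1.45e-05). The GAGA, CAGCTG and CA repeat sequences turned in the same way, at 1.36-fold, 1.24-fold and 1.25-fold. Away from TSSs none of these 3 was higher than in windows of equal A+T content (0.978-fold, 0.992-fold and 1.05-fold, exact adjusted p = 0.963, 0.963 and 0.741). Near TSSs GAGA and CAGCTG were higher than in such windows (1.84-fold and 1.63-fold, exact adjusted p = 0.000163 and 2.24e-06), and the CA repeat did not pass (1.28-fold, 0.199). At summits near a TSS alone 1 consensus sequence was still called lower than in flanks. The calls on CTCF, GAGA and CAGCTG were not made there (0.95-fold, 0.880-fold and 0.907-fold, exact adjusted p = 0.675, 0.394 and 0.367). The GAGA call against flanks was not made with flanks 800 bp away (0.861-fold, exact adjusted p = 0.129), and the poly-A call not within 50 bp of summits (1.06-fold, 0.357). The Pho consensus was lower in both comparisons (0.804-fold and 0.766-fold). It was not called in either comparison at summits near a TSS alone (1.15-fold and 0.918-fold) or at those farther away alone (0.815-fold and 0.780-fold), and its call against flanks was not made without replicate 3 (0.858-fold, exact adjusted p = 0.104) or with flanks 800 bp away (0.837-fold, 0.0509). The Grainyhead consensus, at 21 summits and 43 flanks, was not called without replicate 3 either (0.882-fold, exact adjusted p = 0.708), nor with flanks 800 bp away (0.875-fold, 0.766) or within 50 bp (0.450-fold, 0.0790).

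Among 28998 words of 8 bases, 2747 were more frequent within 50 bp of summits than in flanks and 3684 less frequent (Fisher's exact test, adjusted p under 0.05). Without replicate 3 the less frequent words numbered 2113, and without replicate 2 they numbered 5004. The word with the lowest p was ATATTTTA, at 6.09% of summits and 1.51% of flanks. Against windows of equal A+T content, 24 words were higher and 12 lower. ATATTTTA was then 1.34-fold higher in place of 4.04-fold (exact adjusted p = 0.0338), and the lowest p among the higher words were those of ACACTGAG (48 summits against 8 control windows) and of GGTCACAC, a part of the M1BP consensus (48 against 9).

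Strong peaks were more often near a TSS than weak ones. The share within 500 bp was 51.6% (interval 49.2 to 53.9%) in the 1757 IDR peaks with the highest signal and 32.6% (30.4 to 34.8%) in the 1758 with the lowest (Fisher's exact test, odds ratio 2.20, p = 3.57e-30). ATATTTTA was found within 50 bp at 7.85% and 4.49% of these summits (odds ratio 1.81, exact p = 3.34e-05). The word had been picked from these same peaks, and their A+T content was 70.8% and 64.2%. This difference in the word is therefore not separated from base composition.

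Peaks also lay close to each other. Another summit was found within 1000 bp of 1644 summits (23.4%) against 10.1% with random placement (two-sided permutation p = 0.002, the smallest that 1000 draws can give), but the weakest peaks called on both replicates together had 21.8%, a ratio of 1.07 (Fisher's exact test, p = 0.0252).

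CG15269 itself (FBgn0028878, 2L, 15109405 to 15113092, plus strand) was not bound within 500 bp of its TSS and held no summit within the gene. In the 12000 bp upstream of it, intergenic sequence between CG15269 and wwk, there were 7 IDR summits, the nearest 1936 bp and the farthest 10729 bp from the gene. The strongest had its summit at 15105736 (15105514 to 15105972, signal 803).

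**Figure D5:**
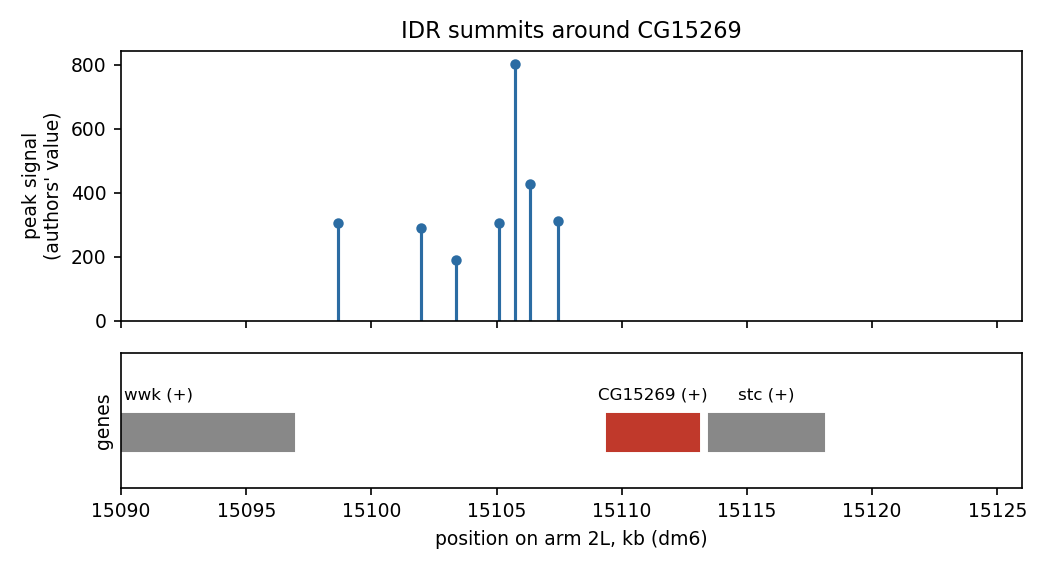
Signal of the IDR peaks, drawn at their summits, along 2L in kb on dm6 (upper panel), and the protein-coding genes with their strands (lower panel, CG15269 in red). The 7 summits lie upstream of CG15269, with the highest signal of 803 at 15105736, and none lies within the gene.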

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

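The tests of A+T content, of promoters used in all cells and of shared promoters were chosen only after the results were seen. The word ACACTGAG was also chosen after its counts were seen.

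Peaks outside the IDR list entered the comparisons above only as references or through the lists of single replicates, and were themselves enriched near TSSs. Of the 22971 peaks called on both replicates together that are not in the IDR list, 15300 had a peak in both replicate lists, which is in part built in since the same reads made all 3 lists. Of these 15300, 22.5% (interval 21.8 to 23.2%) lay within 500 bp of a TSS against 13.6% at random and at most 14.5% in 1000 draws. The DRE was present at 1.05% of their summits and 0.556% of their flanks, and the M1BP consensus at 0.529% and 0.268% (exact sign test, adjusted p = 8.56e-06 and 0.00149), while core promoter motif 6 did not pass (0.804% and 0.634%, adjusted p = 0.183).

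IDR summits were rich in A and T. Base composition of promoters is argued against as the whole cause, since summits farther than 500 bp from a protein-coding TSS had an A+T content 8.40 percentage points above that 1000 bp away. At the weakest peaks called on both replicates together the difference was -0.400 points, which cannot decide on a base-composition bias of the libraries. These peaks were chosen by low signal, and a bias that raises the signal of A+T-rich DNA would keep such DNA out of them. Within the IDR list the A+T content was 70.8% in the 1757 peaks with the highest signal and 64.2% in the 1758 with the lowest. The control alignments were not used here, and no biological explanation was tested because the design has 1 group.

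Ribosomal protein genes were bound more often than other genes. Recovery at any promoter used in all cells is argued against: of 187 translation factor, proteasome and respiratory chain genes 21.9% were bound (interval 16.2 to 28.5%), against 20.3% of other genes. The 3 lists were joined after their counts were seen. Mitochondrial ribosomal protein genes, of which 32.9% were bound, were not among them. Promoters shared with a neighbour do not account for the excess at ribosomal protein genes. With 1 gene counted per peak 62 of 92 were bound, 4.31 times the share of other genes (exact adjusted p = 6.45e-27). A candidate explanation is a site for M1BP or Dref, found within 100 bp of the strongest summit at 25 of 66 bound ribosomal protein genes (37.9%, interval 26.2 to 50.7%) and 205 of 2810 other bound genes (7.30%, exact p = 5.89e-12). Such sites lay within 500 bp of a TSS at 33 of 66 bound (50%) and 9 of 26 unbound ribosomal protein genes (34.6%, exact p = 0.246), so whether they set bound genes apart stays open, as does the level of transcription, which was not analysed here.

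The word ACACTGAG led the words that were higher than in windows of equal A+T content. Exact copies of a repeated element are argued against, since 0% of its 48 occurrences within 50 bp of summits shared their 24 surrounding bases with another. Copies that differ in these bases would not be seen in this way. The word was not nearer to the summits than random positions were. Its median distance was 30.0 bp, against 23.4 bp at random positions, whose medians ranged from 12.0 to 32.5 bp. Summits of the replicates themselves lay a median of 24 bp apart. A bound site need therefore not lie under the summit, and this distance cannot decide on one. The word begins with ACACT, with which the M1BP consensus GGTCACACT ends. Whether its occurrences lie in such sites was not tested. What accounts for the word stays open.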

How the results depend on the processing

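Windows of equal A+T content, 1 gene per peak for head-to-head promoters, TSSs of protein-coding genes and all alternatives for genes without a protein product were chosen after seeing the data; the others were planned. The 7029 strongest peaks called on both replicates together are the IDR list itself, so of 1323 values under alternatives the 199 that used them and the 2 that used ranks in that list could not move and test nothing. Of the other 1122, 989 were counted as unchanged. Values with a test kept their side of the threshold, but a change of direction was not counted where neither value passed. The Zelda consensus, for example, was 0.821-fold against flanks and 1.23-fold against windows of equal A+T content. Counts stayed within a fixed ratio of the main value. The excess of summits near TSSs kept its direction and passed in each alternative run (2.13-fold to 4.15-fold), as did the ribosomal protein list. For the values that changed, the cause was not tested unless stated.

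Replicate agreement was 64.0% with 50% reciprocal overlap, 72.8% with summits within 100 bp, 76.3% when ranked by q and then signal, 83.3% for the strongest 1000, 80.1% for 3514 and 75.0% for 14058 peaks. Using 1 replicate only, arm ratios ranged from 0.905 to 0.959 on 2R, from 1.04 to 1.06 on 3L and from 1.03 to 1.07 on X, and 4 lists were called higher from either replicate against 2 in the main analysis. In the 3514 strongest peaks the 3L ratio was 1.00 and the intron ratio 1.01, both calls being lost, and 1 list was called higher and 3 lower. Against the weakest peaks the intron ratio turned to 0.841. With TSSs within 1000 bp 4 lists were higher. Among genes near any peak called on both replicates together 1 was higher and 2 lower, where fewer genes are tested, and with 1 gene per peak 3 were lower.

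For genes without a protein product, the tRNA fold was 1.61 in the 3514 strongest peaks, where the call was lost, and 1.62 to 3.36 from single replicates, with the call lost without replicate 2. The snRNA fold was 5.76 in the strongest peaks and 3.12 to 3.71 from single replicates, and the snoRNA fold was 2.48 within 1000 bp; the first, the highest of the single replicates and the last passed.

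Near TSSs 1 consensus sequence was lower and Pho turned to 1.15. Against windows of equal A+T content 2 were lower and these turned, with a call in at least the comparison with flanks: CAGCTG 1.24, GAGA 1.36, CTCF 1.41, homeodomain 0.943, Grainyhead 1.05, GATA 0.985, CA repeat 1.25 and poly-A 0.906. Zelda (1.23) and the Twist and Snail E-box (1.11) also turned, but were called in neither comparison. With such windows near TSSs 1 was lower, and CAGCTG was 1.63, CACGTG 1.5, GAGA 1.84, CTCF 1.57, initiator 1.22, homeodomain 0.952, GATA 0.881, CA repeat 1.28 and poly-A 0.928. Away from TSSs 2 were higher and 0 lower, and DRE was 0.792, Zelda 2.30, CTCF 1.32, homeodomain 0.915, Grainyhead 1.33, CA repeat 1.05 and poly-A 0.943. The 2 higher were Zelda and CTCF (Fisher's exact test, adjusted p = 0.0321 and 0.0386). Against flanks 800 bp away Zelda was lower (0.683-fold, exact sign test, adjusted p = 0.0238). In the 3514 strongest peaks it was 0.604-fold against flanks (exact adjusted p = 0.0461). The Twist and Snail E-box was 0.663-fold there (exact adjusted p = 0.0129). Without replicate 2 it was 0.750-fold and away from TSSs 0.754-fold (exact adjusted p = 0.00765 and 0.0461).

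Words more frequent at summits numbered 519 of 6 bases, 1476 of 7 bases, 1000 of 8 bases near TSSs, and, against windows of equal A+T content, 24 in all, 8 near TSSs and 15 away from them. ATATTTTA was then 1.34-fold in all and passed, and 1.14-fold near and 1.43-fold away from TSSs, where it did not. Depth is unknown, so no limit from it can be given.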

Other observations

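All windows below were chosen after the data were seen. The densest 10 kb window of the genome, on 2R from 11190001 to 11200000, held 10 IDR summits within shn, which codes for a zinc finger factor of Dpp signalling. Windows with 8 summits lay at Pdp1 on 3L (7860001 to 7870000), at ftz-f1, a nuclear receptor gene, on 3L (18780001 to 18790000) and on X (7330001 to 7340000), and windows with 7 included ush and bowl on 2L and Hex-A on X. Of 13391 windows, 32 held 6 or more summits, while the fullest window in 100 random placements held 7. Most of the summits in the densest window were away from TSSs, with 1 of the 10 within 500 bp.

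The 12000 bp upstream of CG15269 held 7 summits. Of 11160 windows of that size along the arms, 24 (0.215%) held as many.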
